A study of Mus musculus with 2 samples.

How the data were processed

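H3K4me1 was measured by ChIP-seq in 2 biological replicates of mouse intestine at embryonic day 15.5, each a pool of embryos of both sexes (78 and 62 embryos). The data used here were 4 peak lists in narrowPeak format on mm10: the peaks of replicate 1, the peaks of replicate 2, the peaks of both replicates pooled, and the pooled peaks kept as replicated. The aligner, the peak caller and the rule by which the authors kept a peak as replicated are not given in the sources used here. Per the labels and the notes deposited with each sample, peaks were called by the authors against a control library. The fold values are the authors' signal value of each peak, read as fold over control because the deposited notes name that quantity for the signal track, and were not rescaled here. The -log10 p and -log10 q values of each peak are as deposited by the authors, and no listed peak had a -log10 p under 2. The score of each peak is a display value as deposited by the authors and was not used here. The text notes on each sample served for provenance only. Reads were not used here, so the depth of each library and the precision it gives are unknown, and no interval or floor that needs counts was computed, except where a share of peaks is given with its Clopper-Pearson interval.

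Peaks were placed on the GRCm38 assembly with GENCODE M21 genes, and 0 peaks lay beyond the end of a chromosome. Analyses used 21 chromosomes, and 2 peaks of replicate 2 lay on other sequences. Runs of N of at least 100 bases were taken as gaps. A peak was shared between replicates when an overlap covered at least 50% of the shorter peak. A peak was assigned to a place by its summit for motifs and by its midpoint for location, with a promoter within 1 kb of a protein-coding start, then exons, introns and the space between genes. Random placement put the same peak lengths on the same chromosomes outside gaps, 20 times. Starts were CpG-rich when the window of 500 bases on each side had at least 55% GC and an observed over expected CpG ratio of at least 0.6, and their coverage was read every 50 bases up to 5 kb on each side. The level of a gene was the percent of its locus, the gene with 10 kb on each side, that peaks covered. The median of each of 27 lists was ranked among 10000 random lists of the same size drawn within 20 bins of locus length from 21911 protein-coding genes. Of 477 listed genes, 476 were found in the annotation and Amy2b was not. Lists at or above the 97.5th percentile or at or below the 2.5th were taken as outside the central 95%. The gut and other-organ classes were compared by 10000 shuffles of the labels within 5 strata of locus length. Motif matches were counted on both strands in the central 500 bases of distal peaks and in windows 3 kb away, matched on GC content, and each of 14 motifs was ranked among 100 shuffles of its own letters. Percentiles describe these libraries and are not p-values over samples, since 2 replicates of 1 group allow no test between groups.

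The gene lists, the motifs, the comparisons, the alternatives tried and the rule for naming genes were fixed before the data were examined, except where a setting is said to be chosen after. The rule named the 3 members of each list with the highest percent of locus covered and the 1 with the lowest, the 10 genes with the strongest replicated peak in the gene or within 10 kb of it, the nearest genes of the 10 longest peaks, and the 5 genes with the largest difference between replicates in each direction among loci of at least 20 kb. Hox genes could all be named. The alternatives tried were a -log10 p of at least 5 or at least 10, the pooled list, each replicate's own peaks, other overlaps, promoter distances of 2.5 and 0.5 kb, any overlap with the promoter, all annotated genes, flanks of 0 and 50 kb, random lists matched also on GC content or not matched, the strongest fold value or the share of genes with a peak in place of coverage, flanks not matched on GC, genome windows matched on GC, and the 100000 strongest peaks of each replicate. Alternatives added after seeing the data were random lists matched on length and CpG class of the start, on length within autosomes, and, for the replicate difference, on length and mean coverage or on length and GC content. Leaving out a replicate means that the other replicate's own list took the place of the replicated list. The X chromosome was compared with a random forest of 300 trees, fitted to autosomal bins of 1 Mb on GC content, repeat share and coding genes, with at least 10 bins per leaf. The change in a list's median without flanks was given a percentile interval over 10000 resamplings of its genes, and the matched random lists for smooth muscle genes were drawn again with each of the 19 autosomes left out.

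List coverage, replicate overlap, motif density and peak coverage were tested on simulated data, and the other steps were not. With 10 lists of 20 genes raised 3 times, 10 reached the 97.5th percentile, and of 200 unchanged lists 12 lay outside the central 95%. A planted overlap of 39.44% was recovered as 39.44%, and 100 planted motif sites per 1000 windows as 100.267. Covered bases were equal to a base-by-base count in 1000 of 1000 windows. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, scikit-learn 1.9.0 and matplotlib 3.10.9, and samtools 1.23.1.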

Results

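H3K4me1, a histone mark known to lie at enhancers and beside active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in embryonic mouse intestine at day 15.5, an age when the gut epithelium is starting to form villi. The 2 samples made 1 group and were biological replicates of the same tissue. Replicate 1 came from 78 embryos and replicate 2 from 62 embryos of the B6NCrl strain, with males and females pooled in each. The measurements used here were 4 lists of peaks on the mm10 genome: the peaks of each replicate, the peaks of both replicates pooled, and the pooled peaks kept as replicated. The lists held 160705 peaks for replicate 1, 161615 for replicate 2, 178891 for the pooled data and 104340 in the replicated list. The lists give no read counts, so the depth of each library was unknown here and no interval from read counts could be given. With no second group, the comparisons were between replicates, between groups of genes, and against random placement.

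The 3 strongest H3K4me1 peaks lay in introns of Pcgf2, Ncor2 and Ahdc1. The highest fold value, 8.10, was shared by a peak in an intron of Pcgf2, which encodes a Polycomb group ring finger protein (chromosome 11, 97695353 to 97696769), and a peak in an intron of Ncor2, a corepressor of nuclear receptors (chromosome 5, 125156505 to 125161005). An intron of Ahdc1 carried the longest replicated peak, 8493 bases at a fold value of 7.91 (chromosome 4, 133039976 to 133048468), and peaks covered 55.9% of the Ahdc1 locus (replicates 49.4% ± 2.81, SD, n = 2). Next in strength were peaks nearest Atp2a2, the calcium pump of the sarcoplasmic reticulum (7.63, between genes), Arid1b, a subunit of the BAF remodelling complex (7.54), Mtch1 (7.44), Arhgef17 (7.38), Pxn, which encodes the focal adhesion protein paxillin (7.35), Angel2 (7.25) and Smad7, an inhibitor of BMP and TGF-beta signalling (7.18). After Ahdc1, the longest peaks were nearest Pxn (8371 bases), Bcl9l, a cofactor of beta-catenin (8014), Mef2d (8013), Nol4l (7820), Hspg2 (7465), Csk (7411), Rara, a retinoic acid receptor (7333), Cotl1 (7191) and Glis2 (7124). Replicated peaks had a median length of 397 bases and a median fold value of 2.92, and together covered 55.2 Mb. The fold values are the authors' own, 1 per peak. The replicates' own lists covered 53.4 Mb ± 0.690 (SD, n = 2).

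Peak density differed widely between chromosomes. Chromosome 11, which carries the Hoxb cluster and the Krt19 and Col1a1 genes, had the highest density of replicated peaks, 75.4 per Mb of sequence, and chromosome 3 the lowest of the autosomes, 28.7 per Mb. Chromosome X had 251 replicated peaks, or 1.54 per Mb, and chromosome Y had none listed. Replicate 1 had 2.84 and replicate 2 had 3.54 peaks per Mb on the X, against 43.8 and 45.6 on chromosome 3. The X peaks gathered at few genes: 44 were nearest Bcor, which encodes a corepressor of BCL6, 25 nearest Pja1, which encodes a ubiquitin ligase, and 16 nearest Efnb1, which encodes an ephrin ligand. These 3 genes were picked for mention after their values were seen.

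**Figure D1:**
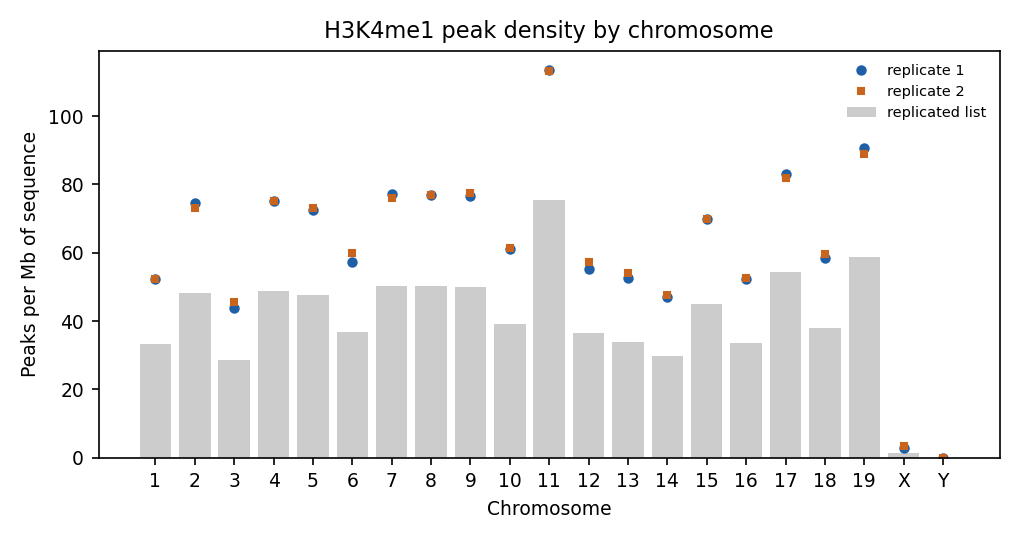
Peaks per Mb of sequence outside assembly gaps (vertical axis) for each chromosome; bars are the replicated list, circles replicate 1 and squares replicate 2. Chromosome X sits at 1.54 replicated peaks per Mb, below every autosome, the lowest of which is chromosome 3 at 28.7.

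How far the 2 pools of embryos gave the same regions was asked by overlapping their own peak lists. At the level of genes the replicates were close: across 21911 protein-coding genes, the percent of each locus covered by peaks had a Spearman rho of 0.960 and a Pearson r of 0.973 between replicates. The difference between replicates had an SD of 1.65 percentage points across these genes. Values were close at some genes: Notch1 was covered at 35.3% in replicate 1 and 36.0% in replicate 2, Ephb2 at 24.6% in both, and Hoxb3 at 39.7% and 39.8%. They were further apart at others, such as Myl7 (34.0% and 23.0%) and Chmp2a (30.4% and 18.5%). At the level of single peaks, 49.1% of replicate 1 peaks and 49.2% of replicate 2 peaks were shared with the other replicate, where a shared peak is overlapped over at least 50% of the shorter peak. Peaks placed at random on the same chromosomes gave 3.09%. The Jaccard index of covered bases was 33.7%, against 1.204% at random. The 2 lists were near equal in number but not in significance. A q under 5% was reached by 88.7% of replicate 1 peaks and 66.0% of replicate 2 peaks. The median -log10 p was 4.82 in replicate 1 and 4.24 in replicate 2. Fold values went the other way, with medians of 2.85 in replicate 1 and 2.90 in replicate 2. Over shared peaks these medians were 3.06 and 3.11, although fold values from lists called separately need not share a scale. Sharing followed strength: with each list parted by -log10 p into 5 equal parts, 81.9% and 81.7% of the strongest part were shared (replicates 1 and 2), and 28.5% and 31.8% of the weakest. Over 73612 shared pairs the fold values had a Spearman rho of 0.320. Both correlations are across genes or peaks of 1 pair of samples, which are not independent replicates, so no p-value is given. The replicated list included 78926 peaks (75.6%) that touched peaks of both replicates and 1489 (1.43%) that touched neither.

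H3K4me1 lay mostly inside genes and away from their starts. Introns held 50.9% of replicated peaks (replicates 51.5% ± 0.291, SD, n = 2) and the space between genes 29.2% (30.7% ± 0.400, SD, n = 2), against 37.1% and 57.2% for peaks placed at random. Promoters, within 1 kb of the start of a protein-coding gene, held 13.7% of replicated peaks against 2.26% at random, a ratio of 6.06. The Gfi1 promoter, which belongs to a regulator of secretory cells, carried the strongest peak of its locus at a fold value of 4.67 (chromosome 5, 107724649 to 107727035), and the promoters of Ephb3 (4.997), Otx1 (4.62) and Sox2 (4.41) did so as well. In the replicates' own lists the promoter share was 11.7% ± 0.00204 (SD, n = 2), lower than in the replicated list by far more than the spread between replicates. Coding exons held 2.78% (random 1.30%), untranslated regions 1.91% (random 1.40%) and other exons 1.53% (random 0.747%). The median distance from a replicated peak to the nearest start was 14.1 kb, against 58.8 kb at random. Each share lay outside the range of the 20 random placements.

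H3K4me1 is known to flank active starts, and its position was measured around 21891 starts of protein-coding genes. At the 8718 CpG-rich starts, the class of Cdx1, Notch1 and Smad7, the mark dipped over the start itself. Peaks covered 9.86% of CpG-rich starts at the start, 24.6% at 650 bases upstream and 38.4% at 1100 bases downstream. The ratio of the value at the start to the highest value was 0.257 (replicate 1, 0.254, and replicate 2, 0.244). At the 13173 CpG-poor starts, the class of Krt19, Col1a1 and Hes1, coverage was 12.1% at the start and 14.2% at 850 bases downstream, a ratio of 0.857 (replicates 0.854 and 0.868). The difference between the classes was larger than the spread between replicates. No test was made of this difference, with 2 replicates.

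**Figure D2:**
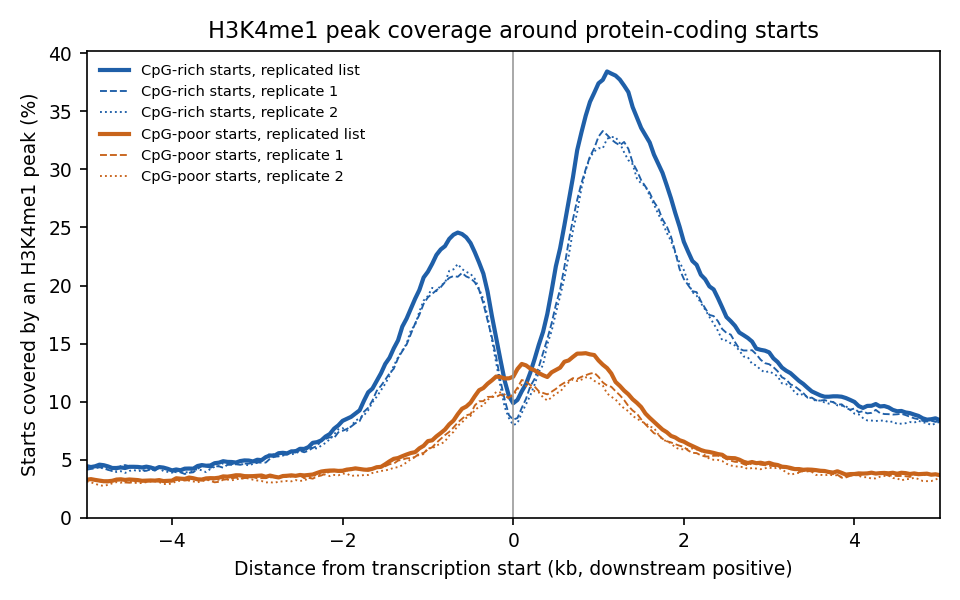
Percent of protein-coding starts covered by a peak (vertical axis) by distance from the start in kb (horizontal axis, downstream positive), for CpG-rich and CpG-poor starts; solid lines are the replicated list, dashed lines replicate 1 and dotted lines replicate 2. CpG-rich starts fall to 9.86% at the start between shoulders of 24.6% and 38.4%, and CpG-poor starts show no such dip.

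Whether genes of the gut's own cell types carried more H3K4me1 than genes of other organs was asked with 27 gene lists, by the percent of each locus (the gene and 10 kb on each side) covered by replicated peaks. Regulators of the gut epithelium were covered at a median of 9.07%, against 2.27% for all protein-coding genes. Cdx1, a homeodomain regulator of intestinal identity, led the list at 36.8% (replicates 31.6% ± 2.98, SD, n = 2; chromosome 18, 61018862 to 61036199), followed by Foxa3 at 29.4% (26.5% ± 0.418, SD, n = 2) and Cdx2 at 16.1% (14.7% ± 2.29, SD, n = 2). Hnf4g, also an epithelial regulator, had no listed peak in its locus in the replicated list or in the list of either replicate. Intestinal stem cell genes reached 9.92%, with the Eph receptors Ephb3 at 26.9% (25.2% ± 3.04, SD, n = 2) and Ephb2 at 25.5% (24.6% ± 0.00271, SD, n = 2) and the Wnt target Sp5 at 16.8%, while Olfm4, a marker of adult crypt cells, was at 1.15%. Gut mesenchyme genes reached 8.005%, with Col1a1 at 27.0% (22.5% ± 1.16, SD, n = 2), Pdgfrb at 25.7% and Barx1 at 21.7%, and Bmp5 lowest at 0.669% (1.18% and 0.762% with replicate 1 or 2 alone). The Pdgfrb and Cdx1 loci overlap and share their strongest peak, at 61041227 to 61041912 on chromosome 18. This peak lay between genes, 3.58 kb from the start of Pdgfrb, the nearest start. These 3 lists lay at the 99.86th, 99.94th and 99.65th percentiles of 10000 random lists of the same size matched on locus length. With 50 kb on each side of a gene, gut epithelial regulators fell to the 94.0th and gut mesenchyme genes to the 76.3rd percentile, inside the central 95%, and by strongest fold value in the locus to the 96.0th and 82.6th.

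The other 7 lists of gut cell types had medians of 1.45% to 6.07%. Enterocyte and epithelial structural genes had a median of 5.24% (94.17th percentile), with the simple-epithelium keratins Krt19 at 31.4% (replicates 27.6% ± 3.40, SD, n = 2) and Krt8 at 26.2% and E-cadherin, Cdh1, at 18.7%, and no replicated peak for Alpi, an alkaline phosphatase of mature enterocytes covered at 2.06% and 0.657% by the peaks of replicates 1 and 2. Smooth muscle genes had 6.07% (97.17th percentile), with tropomyosin Tpm2 at 21.6%, Srf at 21.3% and desmin, Des, at 19.7%, and Flna lowest at 0.384%. Secretory lineage genes had 4.01% (74.5th percentile), led by the goblet cell regulator Spdef at 20.8%, Gfi1 at 18.3% and Insm1 at 17.6%, with none listed for the hormone gene Gcg. Enteric nervous system genes had 4.20% (82nd percentile), with Foxd3 at 18.7%, Hand2 at 12.8% and Erbb3 at 11.7%. Endothelial genes had 4.06% (86.8th percentile), with Egfl7 at 18.6%, Sox18 at 12.9% and Tal1 at 11.99%. Mesothelium and interstitial cell of Cajal genes had 3.62% (76.5th percentile), with Ano1 at 8.54%, and blood and immune genes had 1.45% (27.0th percentile; 2.37% and 0.946% with replicate 1 or 2 alone), with Cd79a at 14.5%. None of these 7 lists lay outside the central 95% of the random lists, but enterocyte genes lay above it in 6 of the 12 alternatives (97.82 and 98.78 with replicate 1 or 2 alone, 99.73 with 50 kb flanks, 99.41 with matching on start class), smooth muscle genes in 5 (98.39 without flanks, 97.93 with 50 kb, 99.11 by start class) and secretory lineage genes in 2 (98.15 without flanks). Matching the random lists on GC content as well put smooth muscle genes at the 63.0th percentile, enterocyte genes at the 43.6th and blood and immune genes at the 1.25th, below the central 95%.

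Of the 11 lists of other organs, forebrain regulators and pancreas genes lay above the central 95% of random lists and the other 9 lay inside it. Liver effector genes had a median of 0.594% (3.72nd percentile), with Ahsg, which encodes fetuin, lacking any listed peak, and germ cell genes had 0.493% (12.6th percentile) and epidermis genes 0% (8.72nd percentile). Stomach and foregut genes had 1.07% (23.9th percentile), with Sox2, a foregut regulator, at 11.5%, Sox21 at 12.8% and Pgc at 13.2%. Skeletal muscle genes had 2.27% (40.3rd percentile), heart genes 2.90% (64.4th), lung genes 3.35% (56.8th), retina effector genes 5.68% (86.5th) and kidney genes 6.92% (96.2nd, and 97.88 and 98.86 with the peaks of replicate 1 or replicate 2 alone, above the central 95%). Forebrain regulators had 10.9% (99.77th percentile), with Bcl11b at 20.6% (replicates 17.6% ± 1.51, SD, n = 2), Otx1 at 18.1% and Neurod2 at 17.2%, and the head regulator Otx2 lowest at 1.44% (2.98% and 1.31% with replicate 1 or 2 alone). Pancreas genes had 9.98% (98.2nd percentile), with Cela1 at 16.9%, Mafa at 16.2% and Cpa1 at 13.9%, and none listed for Iapp. With 50 kb on each side of a gene both lists fell inside the central 95% (forebrain 82.76, pancreas 88.175). The pancreas list passed in only 4 of the 12 alternatives, and fell to the 94.3rd percentile with GC matching and to the 93.4th and 95.8th with the peaks of replicate 2 or replicate 1 alone. With the peaks of replicate 1 or replicate 2 alone, lung genes had 5.39% or 1.40%, heart genes 3.00% or 1.86%, stomach and foregut genes 1.93% or 2.01%, liver genes 0.675% or 1.08%, germ cell genes 0.983% or 1.48% and epidermis genes 0.831% or 1.62%. Some loci of gut lists and of other lists had a strongest peak nearest the start of another gene, which does not show the gene it acts on. How often this happened was not compared between the classes. In gut lists the strongest peak lay nearest Sympk in the locus of Foxa3, nearest Pdgfrb for Cdx1, Krt15 for Krt19 and Hils1 for Col1a1. It also lay nearest Car9 for Tpm2, Speg for Des, Agpat2 for Egfl7 and Arhgef1 for Cd79a. In other lists it lay nearest Bin2 for Cela1, Pbx2 for Ager, a lung gene covered at 49.5%, and Socs1 for the germ cell gene Tnp2.

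Notch pathway, Hox and Wnt pathway genes had the 3 highest medians of the 27 lists. Notch pathway genes had a median of 20.1%, with Nrarp at 44.3% (replicates 35.1% ± 0.579, SD, n = 2), the receptor Notch1 at 40.8% (35.6% ± 0.525, SD, n = 2; chromosome 2, 26457903 to 26516663) and its target Hes1 at 34.4% (29.5% ± 1.19, SD, n = 2), and Rbpj lowest at 2.57%. Wnt pathway genes had 12.9%, with Wnt11 at 26.7%, Fzd7 at 26.4% and Fzd2 at 25.4%, and Apc lowest at 2.67%. BMP and TGF-beta pathway genes had 9.92%, with Smad7 at 50.6% (48.6% ± 1.34, SD, n = 2), Id1 at 45.9% and Smad6 at 41.4%. Hedgehog pathway genes had 8.82%, with the receptor Ptch1 at 19.5%, Sufu at 18.4% and the epithelial ligand Ihh at 15.3%, and Hhip lowest at 0.934%. The 39 Hox genes had 16.4%, and every member had a replicated peak in its locus, from Hoxc12 at 3.77% to Hoxb3 at 47.7% (39.8% ± 0.0460, SD, n = 2) and Hoxb5 at 50.3% (38.0% ± 2.38, SD, n = 2; chromosome 11, 96303336 to 96306121). By cluster, the Hoxb genes had a median of 31.5%, the Hoxa genes 27.8%, the Hoxd genes 13.8% and the Hoxc genes 8.45%. Notch, Wnt and Hox genes lay at the 100th percentile, BMP and TGF-beta genes at the 99.99th and Hedgehog genes at the 99.67th, which fell to the 91.6th with GC matching and the 92.47th with 50 kb flanks. Neighbouring Hox loci can overlap and share peaks, so the coverage of the 39 genes is not independent. The random lists were drawn gene by gene, so the percentile of the Hox list may overstate how far it stands out. Housekeeping genes, a reference for open chromatin, had 7.83% (99.1st percentile) with Eef2 at 40.0%, and passed in 8 of the 12 alternatives. They fell to 96.45 without flanks, 92.99 by strongest fold, 88.205 by share of genes with a peak, and 86.98 with matching on CpG class of the start, a setting chosen after seeing the data.

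**Figure D3:**
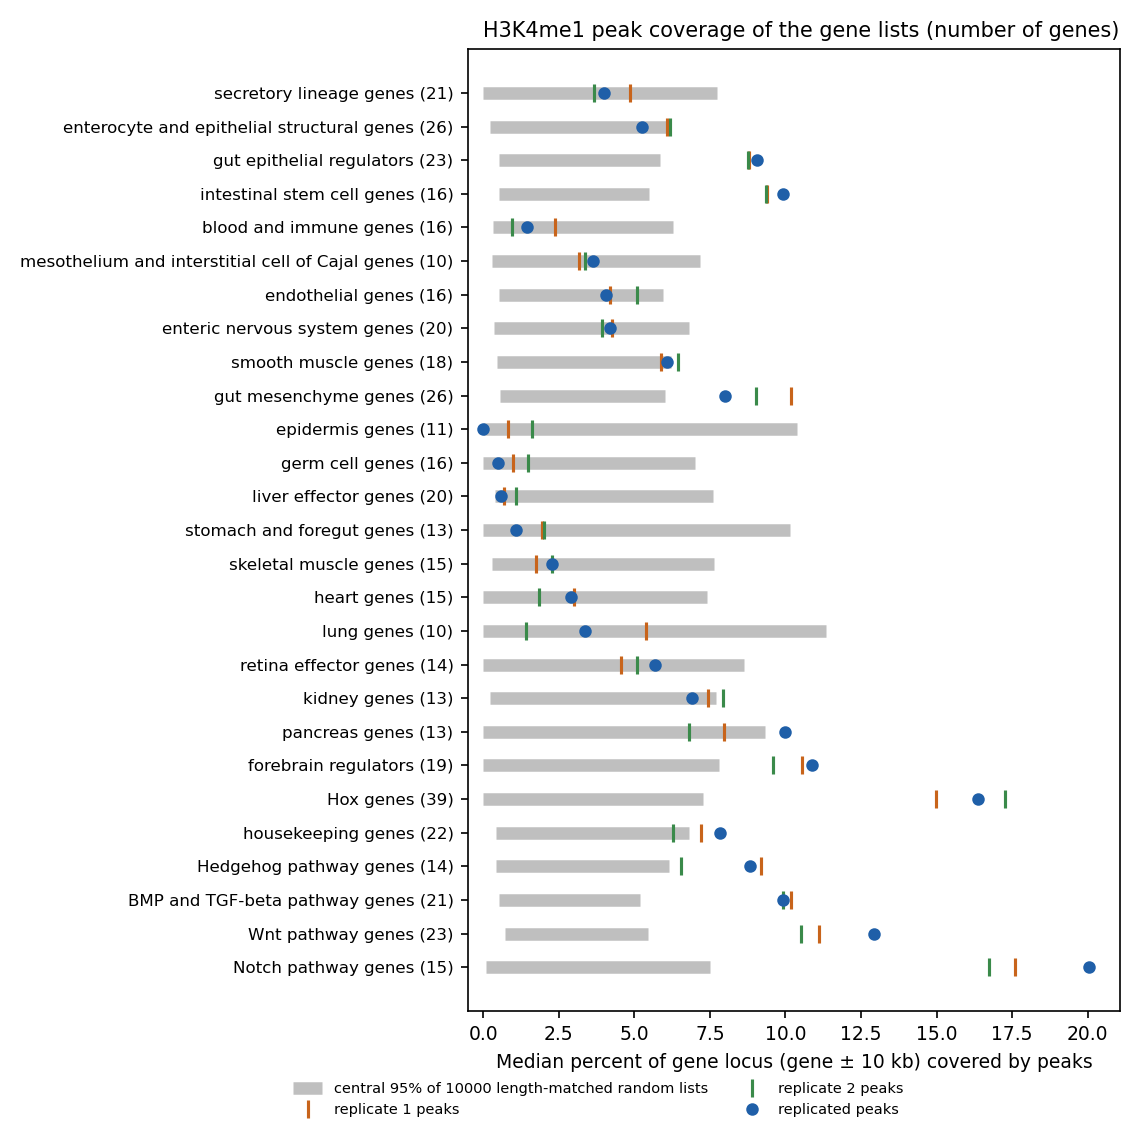
Median percent of gene locus covered by peaks (horizontal axis) for each of the 27 gene lists, with the number of genes in brackets; circles are the replicated list, ticks the peaks of each replicate, and grey bars the central 95% of 10000 random lists matched on locus length. Notch pathway genes are highest at 20.1% and epidermis genes lowest at 0%.

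Pooled together, the gut genes were covered more than the genes of other organs. The 192 genes of the gut lists had a median of 5.84%, and the 159 genes of the other-organ lists had 2.57%. The difference was 3.27 percentage points, 3.45 with the peaks of replicate 1 alone and 3.40 with those of replicate 2 alone. It lay at the 100th percentile of 10000 shuffles of the class labels within strata of locus length, whose central 95% ran from -2.79 to 1.17. With 50 kb on each side of a gene the difference was 0.941 and lay at the 97.46th percentile, just inside the central 95%. The classes were not matched on kind of gene, such as regulators against effector genes. Forebrain regulators (10.9%) and pancreas genes (9.98%) had higher medians than gut epithelial regulators (9.07%), while the remaining other-organ lists were lower. Kind of gene and organ cannot be told apart in this comparison.

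Matches to 4 motifs of gut regulators were denser in distal peaks than in GC-matched flanks, but only the forkhead site passed in all 5 alternatives. Matches to the HNF4 site, bound by the epithelial receptors Hnf4a and Hnf4g, were 1.60 times as dense in peaks as in GC-matched flanks (replicates 1.57 ± 0.0838, SD, n = 2), and matches to the CDX site, bound by Cdx1 and Cdx2, 1.16 times (1.14 ± 0.00117, SD, n = 2). The forkhead site, shared by Foxa factors of the epithelium and Foxf factors of the mesenchyme, reached 1.46 (1.39 ± 0.00616, SD, n = 2), and the GATA site 1.25 (1.203 ± 0.00138, SD, n = 2). The MEF2 site had the highest ratio, 2.10 (1.94 ± 0.122, SD, n = 2), and the TEAD site, read out by the Hippo pathway, reached 1.34 (1.29 ± 0.0232, SD, n = 2). These 6 of the 14 motifs lay above the central 95% of 100 shuffles of their own letters: FOX, TEAD and MEF2 at the 100th, CDX and HNF4 at the 99th and GATA at the 98th. GATA passed in only 1 of the 5, and fell to the 88th percentile against GC-matched windows from across the genome, the 97th in peaks with a -log10 p of at least 10, and the 96th and 97th with replicate 1 or replicate 2 alone. CDX fell to the 86th against the genome windows, and HNF4 to the 90th in the stronger peaks. The other 8 did not pass: the E-box reached 1.31 (97th percentile, and the 100th in the stronger peaks), AP-1 1.16 (94th, and the 98th against genome windows), the Otx and Crx site 1.08 (90th), CTCF 1.98 (86th), ETS 1.24 (80th), the SRF site of smooth muscle genes 1.17 (77th), SOX 0.999 (56th) and REST 0.947 (48th). The central 95% of the CTCF shuffles was wide, from 0.483 to 4.16, so the percentile of CTCF cannot decide whether its site is enriched. The comparison used the central 500 bases of peaks over 1 kb from any start. Before GC matching there were 89969 peak windows and 120243 flank windows, and the GC-matched ratios used 89966 of the peak windows. Without GC matching, the ratios of CDX (0.717), GATA (0.982) and the forkhead site (0.987) were below 1 while their percentiles among letter shuffles were 100.

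**Figure D4:**
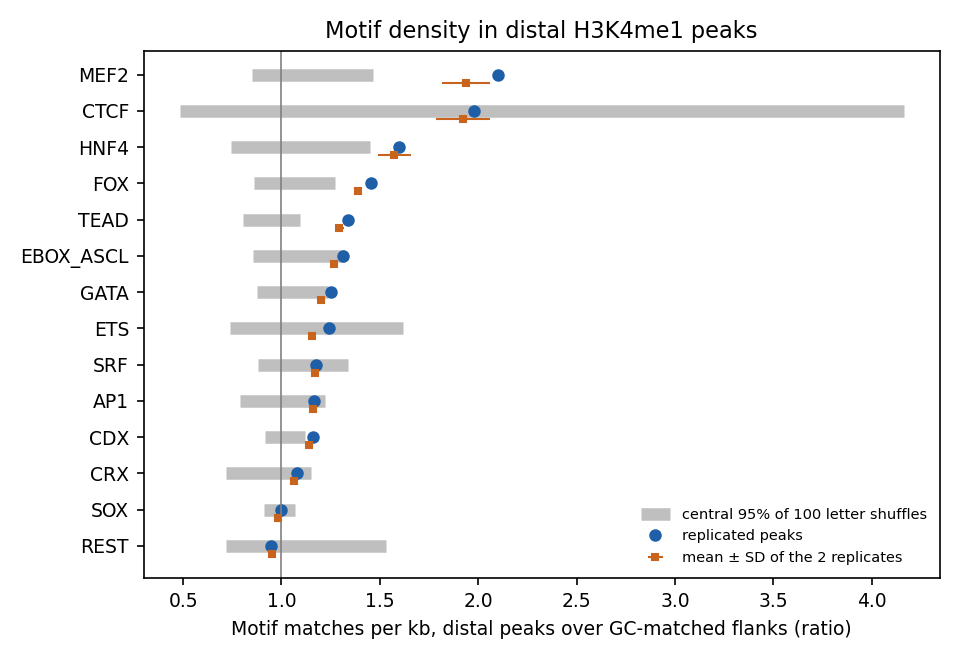
Ratio of motif matches per kb in distal peaks to GC-matched flanks (horizontal axis) for 14 motifs; circles are the replicated list, squares with bars the mean and SD of the 2 replicates, and grey bars the central 95% of 100 letter shuffles of each motif. MEF2 is highest at 2.10, and CTCF at 1.98 stays inside the wide range of its shuffles (0.483 to 4.16).

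Whether a gut compartment or a neighbouring organ differed between the 2 pools was asked by the difference in percent of locus covered, replicate 2 minus replicate 1. Hox genes were covered more in replicate 2, by a median of 2.33 percentage points, with 31 of the 39 genes higher. Loci of neighbouring genes in a Hox cluster can overlap and share peaks, so the 39 genes are not independent. The median of the gene differences was 2.40 for Hoxa, 1.12 for Hoxb, 2.55 for Hoxc and 2.503 for Hoxd genes. The Hoxc4 locus, for example, was covered at 16.5% in replicate 1 and 24.9% in replicate 2. The median coverage of Hoxa genes was lower in replicate 2 (23.9%) than in replicate 1 (25.0%), although 9 of the 11 genes were higher. For Hoxb, Hoxc and Hoxd genes the median coverage was higher in replicate 2. Smooth muscle genes were also higher in replicate 2, by 0.443. Enterocyte and epithelial structural genes were lower in replicate 2 (-0.784), as were gut epithelial regulators (-0.654), mesothelium and interstitial cell of Cajal genes (-0.770), BMP and TGF-beta genes (-0.678), Notch genes (-0.986) and housekeeping genes (-0.849). These 8 lists lay outside the central 95% of random lists matched on length, and the other 19 lists did not. Matching on mean coverage as well, a setting chosen after seeing the data, left only the Hox list outside (100th percentile), with smooth muscle genes at the 97.49th, enterocyte genes at the 4.22nd and gut epithelial regulators at the 15.7th. With the 100000 strongest peaks of each replicate, BMP, mesothelium and housekeeping genes fell inside the central 95% (17.475, 91.16 and 3.21). Measured by the strongest fold value in each locus, BMP genes were higher in replicate 2 instead (0.669, 99.94th percentile), Hox genes stayed higher, and the other 6 lists lay inside the central 95%, although fold values from lists called separately need not share a scale. Of these, enterocyte genes (0.289, 97.46th percentile) and Notch genes (0.438, 96.96th) lay near its upper bound, on the side of replicate 2. The largest differences at genes fell in replicate 2 at G430095P16Rik (-11.96), Chmp2a (-11.9), Gm48552 (-11.7), Fads3 (-11.5) and Emilin1, which encodes an elastic fibre protein (-11.1). They rose at Fjx1 (11.3), Aurkb, a mitotic kinase (9.54), Trhr2 (9.21), Hspb2 (9.18) and Rpl35 (8.48). With 1 pair of samples, no p-value can be given for any of these differences.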

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

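The settings matched on mean coverage, on GC content for the replicate difference, on CpG class of the start, and on length within autosomes, and the peak counts with a replicate left out, were chosen after seeing the data. Every value below changed by the alternative's own construction (other peaks, windows or matching) or, where none is named, the cause was not tested.

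With a -log10 p of at least 10, replicated peaks fell to 21009, the overlap between replicates to 38.9% and the promoter share rose to 18.9%, with the start ratio at CpG-rich starts at 0.285. The lower overlap came from filtering both lists: 95.6% and 96.0% of peaks this strong lay in the other replicate's full list. A -log10 p of at least 5 gave an overlap of 48.2%. The pooled list gave 178891 peaks, a promoter share of 11.4% and a start ratio of 0.248. Leaving out a replicate gave 160705 to 161615 peaks, a promoter share of 11.7% either way and start ratios of 0.244 to 0.254. An overlap of at least 1 base gave 56.6% shared and 50% of both peaks 30.3%. Promoters within 2.5 kb held 25.5% of peaks and within 0.5 kb 6.68%, any overlap with the window gave 17.2%, and starts of all annotated genes 17.5%.

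The number of gene lists above the central 95% of random lists, 11 in the main setting, stayed between 8 and 13 except by strongest fold (7). Of these 11 lists, 5 (intestinal stem cell, BMP and TGF-beta, Hox, Notch and Wnt) passed in all 12 alternatives. With flanks of 50 kb, 5 of the 11 no longer passed: gut epithelial regulators, gut mesenchyme, forebrain, pancreas and Hedgehog genes. With GC matching, 3 lists not called in the main setting fell below the random lists at unchanged medians: heart (2.90%, 0.745th percentile), blood and immune (1.25th) and stomach and foregut genes (2.09th). Liver effector genes fell below within autosomes (1.7th). The gut lists stayed above other organs in every alternative, but with flanks of 50 kb the difference of 0.941 no longer passed. The number of motifs that passed was 5 or 6 throughout, and 3 of the 6 (FOX, MEF2 and TEAD) passed in all 5 alternatives.

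The number of lists that differed between replicates was 8, 7 with the 100000 strongest peaks of each, 3 by strongest fold, 1 with coverage matching and 3 with GC matching. By strongest fold, the BMP and TGF-beta list (0.669) turned from lower to higher in replicate 2 and passed. The values of the Notch (0.438, 96.96th percentile), enterocyte (0.289, 97.46th), gut epithelial regulator (0.0271, 66.01st) and mesothelium (0.383, 90.13th) lists changed sign inside the central 95% of random lists. The enterocyte list lay too near the upper bound to decide. With the strongest 100000 peaks, the mesothelium value changed sign inside the central 95% (0.199), the Hedgehog list became lower (-1.22, 0.02nd percentile) and the intestinal stem cell list higher (0.247, 97.85th). Heart genes became lower by strongest fold (-0.300). Of the named genes' values, 231 stayed within the replicate SD and 777 moved beyond it. Read depth was not used here, so what it limits is unknown.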

Other observations

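The tests of the X chromosome's content and of random runs of neighbouring genes at the Hox clusters were set before their results were seen. The settings without flanks, with 50 kb flanks, with 1 replicate alone, with GC matching for list coverage, by strongest fold and with equal numbers of peaks were fixed before the data were examined, but what they would show for each explanation was written after. The remaining tests were chosen after. The design has 1 group, so no biological difference between groups was tested, and a dose of active X at 0.5 of the autosomes is the only biological explanation with a test. The test on dose was revised after its first results were seen, and the replicate tests were first set for 4 lists together and then split into Hox, the epithelial lists and smooth muscle.

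Peaks were scarce on the X chromosome, at 1.54 replicated peaks per Mb. The tables argue against sequence and gene content as the whole cause, because a model of the autosomes predicted 11.2 per Mb from the X's GC content, repeats and genes, and the observed count was 0.138 of that, where autosomes left out of the model ranged from 0.838 to 1.16. The left-out autosomes do not test the model at the repeat share of the X, 46.7%, since the highest autosome, chromosome 3, had 35.8%. For repeats the argument is therefore weak. Raised control signal on the X stays open. Fold values on an evenly spaced series were held by 89.6% of X peaks (95% Clopper-Pearson interval 85.2 to 93.1), against 38.5% of autosomal peaks. This series was read as that of peaks scored against a genome-wide background, an assumption, since the peak caller is not given. Only 51 of 167 bins of the X held a peak, so sites without peaks were not seen. A dose of active X at 0.5 of the autosomes, in pools of both sexes where males have 1 X and females silence 1, may account for the scarcity. Halving the fold of autosomal peaks on the evenly spaced series left a share 1.07 times the observed X ratio. For all autosomal peaks that share was 3.58 times the ratio. After the correction for content the values were 0.274 on the series and 0.917 for all autosomal peaks. This dose cannot be told apart from other causes, because the result depends on the peaks used, the lowest fold value assumed and the correction for content. Its 12 forms ranged from 0.136 to 4.33, and 6 lay within 2 times of the observed.

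Replicate 2 was lower at 6 lists, of which enterocyte genes (-0.784) and gut epithelial regulators (-0.654) were weighed here, and higher at smooth muscle (0.443) and Hox genes (2.33); Notch (-0.986), housekeeping (-0.849), mesothelium (-0.770) and BMP genes (-0.678) were not weighed. For the 4 weighed lists the tables argue against unequal numbers of called peaks as the whole cause. The full lists, at 160705 and 161615 peaks, left little room for it. With the 100000 strongest peaks of each, the differences shrank to -0.493, -0.407, 0.249 and 1.54. The 3 lists other than Hox stayed outside the central 95% and Hox at the 100th percentile. BMP (-0.0566), mesothelium (0.199) and housekeeping genes (-0.413) fell inside. Unequal significance of peaks, by -log10 p, stays open for all of these lists. A -log10 p of at least 5 was reached by 72768 peaks of replicate 1 and 60080 of replicate 2, and equal numbers do not remove that. For Hox the tables also argue against coverage (100th percentile with matching) and GC content (100th). Overlap between clustered loci stays open. Hox genes lay at the 100th percentile among 10000 sets of 4 random runs of neighbouring genes. Among runs with at least 0.5 of each cluster's mean coverage they lay at the 99.99th. These runs were not matched on spacing, so their loci need not overlap as those of Hox genes do. For smooth muscle the tables argue only against a shift of the median with coverage or GC content. The matched random medians lay at -0.440 and -0.259 of its rise, on the other side of 0 whichever autosome was left out. Leaving out 1 autosome changes such lists little, so this adds little. The list itself fell inside both matched spreads (97.49 and 96.75), so a wider spread at such loci stays open. For the 2 epithelial lists coverage and GC bias stay open, since 0 of the 2 stayed outside with either matching, where the random lists spread more widely (for enterocyte genes from -0.402 to 0.0808 with length alone and -0.886 to 0.347 with coverage) and their medians moved by less than 0.5 of each difference; smooth muscle genes fell inside that wider spread too (97.49 and 96.75). Tissue shares in the pools were not tested: housekeeping (2.2nd percentile) and BMP genes (1.75th) also fell and stayed outside with GC matching. By strongest fold only BMP of the 6 lower lists lay outside the central 95%, and was higher in replicate 2 (0.669, 99.94th). Enterocyte genes lay just inside it, also on the side of replicate 2 (0.289, 97.46th).

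Forebrain regulators and pancreas genes lay above random lists in an intestine sample. The tables argue against CpG-rich starts as the whole cause, because with matching on start class the lower of the 2 percentiles was 97.83 (SE from the random draws 0.146), and for forebrain regulators against GC content (99.395 with matching) and peaks of neighbouring genes in the flanks (99.99 without flanks). That SE does not cover the choice of genes, and the forebrain median of 10.87 lay close to the upper bound of 10.72 with start class. The forebrain random median rose from 2.61 to 5.36 with start class and to 5.56 with GC matching, so either may carry a part. Flank peaks stay open for the pancreas list: without flanks its median rose by 2.698 points to 12.68, but the 95% interval over resampled genes ran from -5.92 to 15.8, and the percentile of 97.585 (SE 0.154) was too near the bound to decide. GC content stays open for the pancreas list too, at 94.255 with GC matching, where the random median rose from 2.71 to 5.61. With 50 kb flanks both lists fell inside the central 95% (82.76 and 88.175), and the pancreas list did so with the peaks of replicate 2 or replicate 1 alone (93.42 and 95.78), so tissue of another organ in the pools can be neither shown nor ruled out.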
